A study of Homo sapiens with 8 samples.

How the data were processed

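The series holds 8 arrays with 2 dyes each, made from total RNA of 16 cultures of LHCN-M2 myotubes, 4 per condition. Samples were grouped by the labels into control, palmitate, oleate and mixture. Each RNA was hybridised once, and each condition was labelled 2 times with each dye. All 8 arrays lay on 1 slide and were scanned together, with the 4 arrays that carried palmitate in one of its columns.

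The authors scanned and quantified the arrays with Agilent Feature Extraction 10.7.3.1. Per the file headers, the spot and background signals are median pixel intensity values in each channel, before background subtraction. Per the file headers, the log ratio column holds the log10 of Cy5 over Cy3 after background subtraction, detrending and dye normalization by Feature Extraction. That program sets the ratio of weak spots to 0, which applied to between 8435 and 10799 spots per array that were not controls. The deposited value table holds the log2 of Cy5 over Cy3. Its base of the log was inferred by comparison with the scanner values, and its background correction and normalization are not stated. Its columns correlated at r = 0.993 to 0.996 with the ratios computed here, across probes above background in all 16 channels. Its column medians lay between -0.000963 and 0.00911.

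Median signals were background-corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with jsonlite 2.0.0 and version 1.17.8 of data.table. The design had set mean signals, but the files held no such column, so median signals were used throughout. Control spots, and spots marked as non-uniform or as population outliers, were left out. The spots of a probe were averaged, and a probe was tested if it was well above background in at least 4 of 16 channels. Of 42405 probes, 27865 passed, and 22398 were above background in all 16 channels. Probes were given a gene symbol by their RefSeq accession, which matched 26364 probes to 1 symbol each. A gene was represented by its brightest probe over all arrays, and probes without a symbol were tested as themselves, which left 14746 genes and 8388 unnamed probes. Of the unnamed, 3768 were probes for long intergenic noncoding RNA, placed on the build hg19 per the file headers. Loess within arrays takes rises and falls to balance, and the amount of RNA per cell was not measured, so changes are relative to the bulk of the genes. The offset draws the ratios of dim probes toward 0.

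The log2 ratios were fitted in limma with 3 coefficients for the conditions and a common dye intercept, without a block or slide term. The fit left 4 residual degrees of freedom per gene and borrowed 5.60 from the other genes. Moderated p-values were adjusted by Benjamini-Hochberg over the 23134 genes and unnamed probes, with a threshold of 0.05. Comparisons that shared arrays (palmitate with control, palmitate with oleate, mixture with oleate, mixture with control) had a median standard error of 0.0579, and those through other conditions (oleate with control, mixture with palmitate) 0.0668. The mixture was also tested against the midpoint of palmitate and oleate, and a moderated F test asked for any difference. Levels quoted per condition were taken from single channels after loess and quantile normalization of the average intensity, so that their differences depart slightly from the fitted changes. The number of arrays limits the precision.

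The labels number the replicates within each condition, and nothing in them says that a number marks a shared culture or day. A fit with the replicate number as a block was run as an alternative.

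On simulated data built from the fitted spread, the fit recovered 76% of spiked genes at 1.25-fold and 100% at 2-fold for palmitate against control, and 42% and 100% for oleate against control. Of its calls on these data, 8.82% and 7.65% were false, more than the threshold of 0.05 aims at. Only 50 of 23124 genes were changed at each fold there, where 62.9% passed for palmitate against control in the real data. The shares recovered and false need not carry over to the real data.

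A total of 32 gene lists were fixed before the data were examined. They were PPAR targets and fatty acid oxidation, lipid droplet and glyceride synthesis, cholesterol synthesis and SREBP2 targets, fatty acid synthesis and desaturation, LXR and cholesterol efflux, ATF4 and integrated stress response, endoplasmic reticulum chaperones and XBP1 or ATF6 targets, NF-kB and inflammatory cytokines, interferon response, mitochondrial respiratory chain, mitochondrial biogenesis regulators, glycolysis, hypoxia targets, insulin signalling, sphingolipid and ceramide synthesis, NRF2 antioxidant targets, metallothioneins, heat shock proteins, contractile and mature myotube genes, myogenic regulators and fusion, muscle atrophy and ubiquitin ligases, autophagy and lysosome, apoptosis and p53 targets, proliferation and cell cycle, extracellular matrix, circadian clock, immediate early genes, glucocorticoid targets, myokines and secreted factors, and markers of fibroblasts, of adipocytes, and of endothelial and blood cells. Some genes belong to several lists. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 32 lists within a comparison. The same test with an estimated correlation and fry were run beside it. A member rose or fell when it passed over all genes tested, and counts adjusted over the list alone are given beside.

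The genes named were set by a rule. It took the 8 largest rises and the 8 largest falls for palmitate, oleate and mixture against control and for palmitate against oleate, and the 4 largest each way in the others, among genes past the threshold with the same sign in all 8 fits that leave out 1 array. It added the 4 members with the smallest p of each list that passed or had at least 2 members past the threshold, and genes named in advance, of which 11 are reported (PDK4, ANGPTL4, CPT1A, PLIN2, SCD, HMGCS1, INSIG1, DDIT3, TRIB3, IL6 and CXCL8). The single results of a few genes that the rule picks are left out, and these genes stay members of their lists.

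Alternatives covered the ratios (no background subtraction, Feature Extraction log ratios, the deposited value table, scale normalization between arrays, median centring in place of loess), the probes (no filter on dim probes, only probes above background in all 16 channels, the mean of all probes of a gene), and the fit (array quality weights, no dye intercept, a dye term per slide column, the replicate block, direct arrays alone, separate channels, each array left out in turn). Other groupings of the RNAs were fitted as well, with a seed of 11 where they were drawn.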

Results

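Myotubes of LHCN-M2, an immortalised line of human skeletal myoblasts, were exposed for 16 h to a saturated fatty acid, a monounsaturated fatty acid, or both. The exposure began 10 days after differentiation was induced. The 4 conditions, with 4 biological replicates each, were a control, palmitate at 0.5 mM, oleate at 0.5 mM, and a mixture with each fatty acid at 0.25 mM. The fatty acids were given as sodium salts bound to albumin, and the labels do not state whether the control medium held the same albumin. Total RNA was hybridised to 8 Agilent arrays with 2 dyes, so that each of the 16 RNAs was measured on 1 array. The arrays formed a loop in which palmitate met control, palmitate met oleate, oleate met mixture and mixture met control, on 2 arrays each with the dyes exchanged. Oleate and control, and mixture and palmitate, never shared an array.

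Each array carried 62976 spots, of which 58717 were not controls. Between 62.4% and 67.9% of these spots lay above background in a channel. The share was 65.6% ± 2.0 in control, 64.1% ± 1.1 in palmitate, 66.4% ± 1.2 in oleate and 65.0% ± 1.7 in mixture (SD, n = 4). After a filter on signal, 23134 genes and unnamed probes were tested, 14746 of them with a gene symbol. The limma test of any difference among the 4 conditions passed an adjusted p of 0.05 for 15175 of them (65.6%). The 4 direct differences around the loop should sum to 0 if arrays add up. The limma test of that sum passed for 0 of 23134 genes, with 584 at an unadjusted p under 0.05 where 1156.7 would be expected by chance. The test was thus conservative. It judged the sum by dye differences between array pairs, whose residual SD was 0.124 on the log2 scale, against 0.106 from the sum. A log2 change is given with its standard error from the fit, and a level is a log2 intensity with its SD over 4 RNAs.

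**Figure D1:**
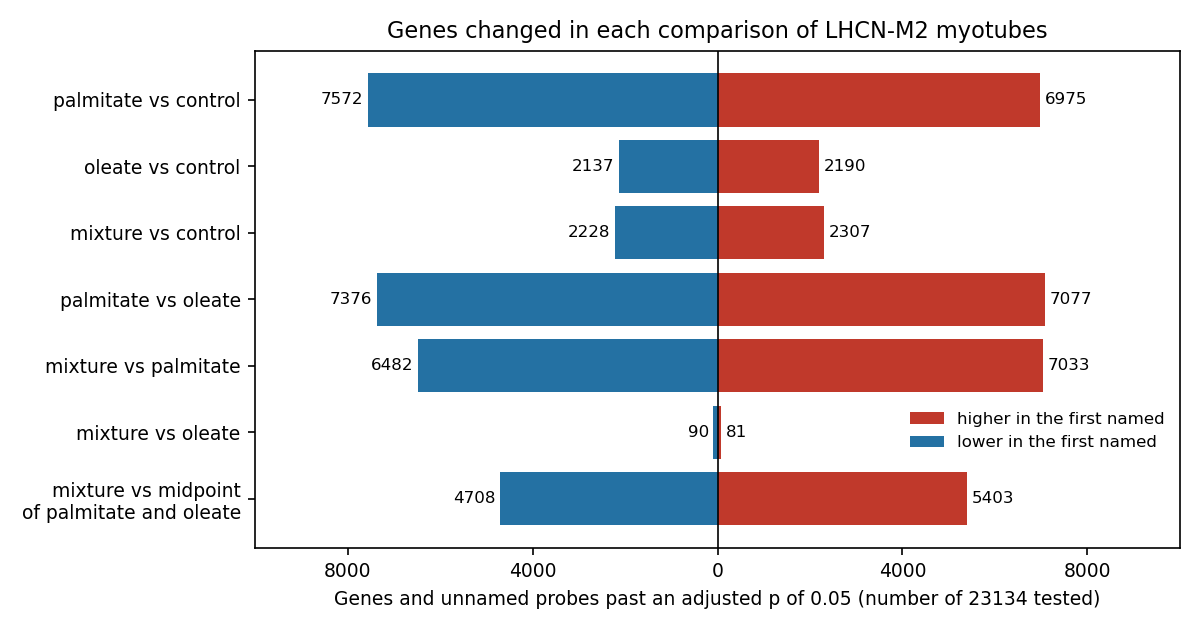
Number of genes and unnamed probes past an adjusted p of 0.05 in each comparison (horizontal axis), with those higher in the first named condition to the right and those lower to the left. Palmitate differed from control at 14547 of 23134, the mixture from oleate at 171.

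The effect of 0.5 mM palmitate was asked by comparing it with control. IL6, which encodes a cytokine that muscle can secrete, rose 79.3-fold (log2 change 6.31 ± 0.10, adjusted p = 1.1e-10). Its level was 16.99 ± 0.25 with palmitate and 10.49 ± 0.24 in control (n = 4 each), where 1 control RNA stood apart at 10.84. The neutrophil chemokine CXCL8 rose 43.1-fold, from a level of 8.83 ± 0.08 to 14.25 ± 0.09. TRIB3, a target of the stress factor ATF4, rose 29.5-fold, and DDIT3, the factor CHOP of the same pathway, rose 9.50-fold. ACTA1, which encodes the actin of the skeletal muscle thin filament, fell from 15.93 ± 0.34 to 12.44 ± 0.27 (log2 change -3.64 ± 0.09, adjusted p = 4.5e-10).

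In all, 14547 genes and unnamed probes changed with palmitate (62.9%), 6975 higher and 7572 lower. The change was over 2-fold for 2825 of them and over 4-fold for 475. The 8 largest rises were those of IL6, CCL3 (5.71 ± 0.07), CXCL8 (5.43 ± 0.05), HSPA6 (5.19 ± 0.06), C11orf96 (5.18 ± 0.09), CCL20 (5.08 ± 0.07), TRIB3 (4.88 ± 0.08) and CSF3 (4.59 ± 0.10). CCL3 and HSPA6 each have near-identical relatives, so their probes may hold signal from both copies. The 8 largest falls were those of CDKN1C (-3.85 ± 0.07), ACTA1, TNFSF10 (-3.62 ± 0.14), MYH3 (-3.61 ± 0.06), DMBT1 (-3.58), APOBEC2 (-3.35), MYH7 (-3.33 ± 0.08) and FBXL22 (-3.31). CDKN1C encodes a cell cycle inhibitor of differentiating muscle, and MYH3 and MYH7 encode the embryonic and the slow myosin heavy chain.

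Among genes that fatty acids are known to regulate, palmitate raised ANGPTL4, a secreted lipase inhibitor under PPAR control, 15.8-fold (3.98 ± 0.09). The lipid droplet coat gene PLIN2 rose 7.92-fold, CPT1A of mitochondrial fatty acid import rose 1.87-fold and PDK4, which restrains glucose oxidation, rose 1.83-fold. PDK4 was above background in 2 of the 4 control channels. The desaturase SCD (-1.68 ± 0.07) and the sterol synthesis gene HMGCS1 (-1.48 ± 0.05) fell, as did INSIG1 of the sterol feedback loop (-0.52 ± 0.05).

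The list of ATF4 and integrated stress response genes rose, with 25 of 28 higher and 1 lower (26 and 1 when adjusted over the list alone; median 1.89, camera adjusted p = 1.5e-31). ATF3 (3.88), CTH (2.93) and MTHFD2 (2.60) were among them. Endoplasmic reticulum chaperones and XBP1 or ATF6 targets rose, 26 of 29 higher and 2 lower (the same counts adjusted over the list alone; median 1.28, adjusted p = 4.2e-19), with DNAJB9 at 4.44 and HERPUD1 at 2.53. Both list calls held with an estimated correlation (adjusted p = 0.0312 each).

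The 16 other list calls for palmitate against control rested on the preset correlation. Immediate early genes rose (21 of 22, 1 lower; median 1.78), FOSB by 3.22 and FOSL1 by 3.05, and had an adjusted p = 0.145 with an estimated correlation. Heat shock proteins rose (18 of 20, 2 lower; median 1.92), DNAJB1 by 2.95 and HSPH1 by 2.88 (adjusted p = 0.142 with an estimated correlation). NF-kB and inflammatory cytokines rose (26 of 33, 6 lower; median 1.35), with CXCL2 at 3.05 (adjusted p = 0.265 with an estimated correlation). NRF2 antioxidant targets rose (22 of 24, 1 lower; median 1.22), SRXN1 by 3.82 and TXNRD1 by 2.75 (adjusted p = 0.0888 with an estimated correlation). Myokines and secreted factors rose (11 of 18, 6 lower; median 0.77), LIF by 3.12 (adjusted p = 0.24 with an estimated correlation). Hypoxia targets rose (14 of 19, 3 lower; median 0.50), ADM by 2.36 (adjusted p = 0.278 with an estimated correlation). Autophagy and lysosome genes rose (14 of 25, 8 lower; median 0.24, 0.16 to 0.34 over the settings), SQSTM1 by 1.82 (adjusted p = 0.347 with an estimated correlation). Adjusted over the list alone, 9 autophagy genes were lower and the counts of the other 6 lists stayed as given.

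Contractile and mature myotube genes fell (37 of 43, 4 higher; median -1.66, adjusted p = 1.1e-27), MYL1 at -3.20, TNNC2 at -3.19 and TNNI2 at -3.14. Their adjusted p = 0.24 with an estimated correlation. Myogenic regulators and fusion genes fell (18 of 23, 2 higher, 3 when adjusted over the list alone; median -1.30). MYOD1, a master regulator of the muscle lineage, fell by 3.16 and MYOG by 1.83 (adjusted p = 0.142 with an estimated correlation). Cholesterol synthesis and SREBP2 targets fell (26 of 28, 0 higher; median -0.93), with MVK at -2.30 and ACAT2 at -1.96 (adjusted p = 0.162 with an estimated correlation). Fatty acid synthesis and desaturation genes fell (12 of 19, 5 higher, 13 lower when adjusted over the list alone; median -0.81; adjusted p = 0.278 with an estimated correlation). Markers of fibroblasts fell (9 of 12, 2 higher; median -0.998), COL3A1 at -3.26 and THY1 at -2.57 (adjusted p = 0.347 with an estimated correlation). Extracellular matrix genes fell (20 of 29, 7 higher; median -0.78), although CCN1 rose by 3.93 (adjusted p = 0.278 with an estimated correlation).

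Falls passed for 3 further lists. Proliferation and cell cycle genes fell (23 of 33, 5 higher; median -0.30, -0.76 to -0.23 over the settings), TYMS at -1.77 (adjusted p = 0.249 with an estimated correlation). Interferon response genes fell (15 of 23, 3 higher, 16 lower when adjusted over the list alone; median -0.46), BST2 at -1.80. Their adjusted p = 0.396 with an estimated correlation, and the call was also lost without a dye intercept. Mitochondrial respiratory chain genes fell (23 of 30, 2 higher; median -0.41, adjusted p = 0.0472), ATP5F1A at -1.22, while CYCS rose by 1.68. Their adjusted p = 0.114 with an estimated correlation, and the call was lost under 12 of 23 other settings in all, the arrays of palmitate with control taken alone among them.

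The other 14 lists did not pass for palmitate against control. In PPAR targets and fatty acid oxidation 10 of 33 rose and 15 fell (adjusted p = 0.332), with UCP2 at -2.36 and HADH at -1.88. In lipid droplet and glyceride synthesis 8 of 25 rose and 15 fell (FITM1 -2.79), in LXR and cholesterol efflux 3 of 11 rose and 7 fell (ABCA1 1.33, NR1H3 -1.68), and in glycolysis 9 of 23 rose and 13 fell (HK2 1.54, PGAM2 -2.47). Insulin signalling had 10 of 26 higher and 13 lower (IRS2 1.69, FOXO1 -1.79), and its median of -0.16 and mean of 0.08 differed in sign. Mitochondrial biogenesis regulators had 6 of 20 higher and 6 lower (PPARGC1B -2.03), again with a median (-0.04) and mean (0.06) of opposite sign. Sphingolipid and ceramide synthesis had 9 of 25 higher and 11 lower (SPHK1 1.64, CERS1 -1.94). Apoptosis and p53 targets had 8 of 21 higher and 10 lower (GADD45A 2.10, TP53I3 -2.39). Muscle atrophy and ubiquitin ligases had 8 of 16 higher and 5 lower (CBLB 1.58), and the circadian clock 9 of 17 higher and 8 lower (RORA 2.10, BMAL1 1.59). Glucocorticoid targets had 8 of 14 higher and 5 lower (DUSP1 2.56, TSC22D3 -2.30). Metallothioneins, whose members share near-identical sequences, had 5 of 11 higher and 2 lower. Markers of adipocytes had 2 of 8 higher and 1 lower (PPARG 1.22), and markers of endothelial and blood cells 0 of 11 higher and 6 lower (CD68 -1.20). Adjusted over the list alone, the counts differed only for p53 targets (9 higher) and glucocorticoid targets (6 lower).

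**Figure D2:**
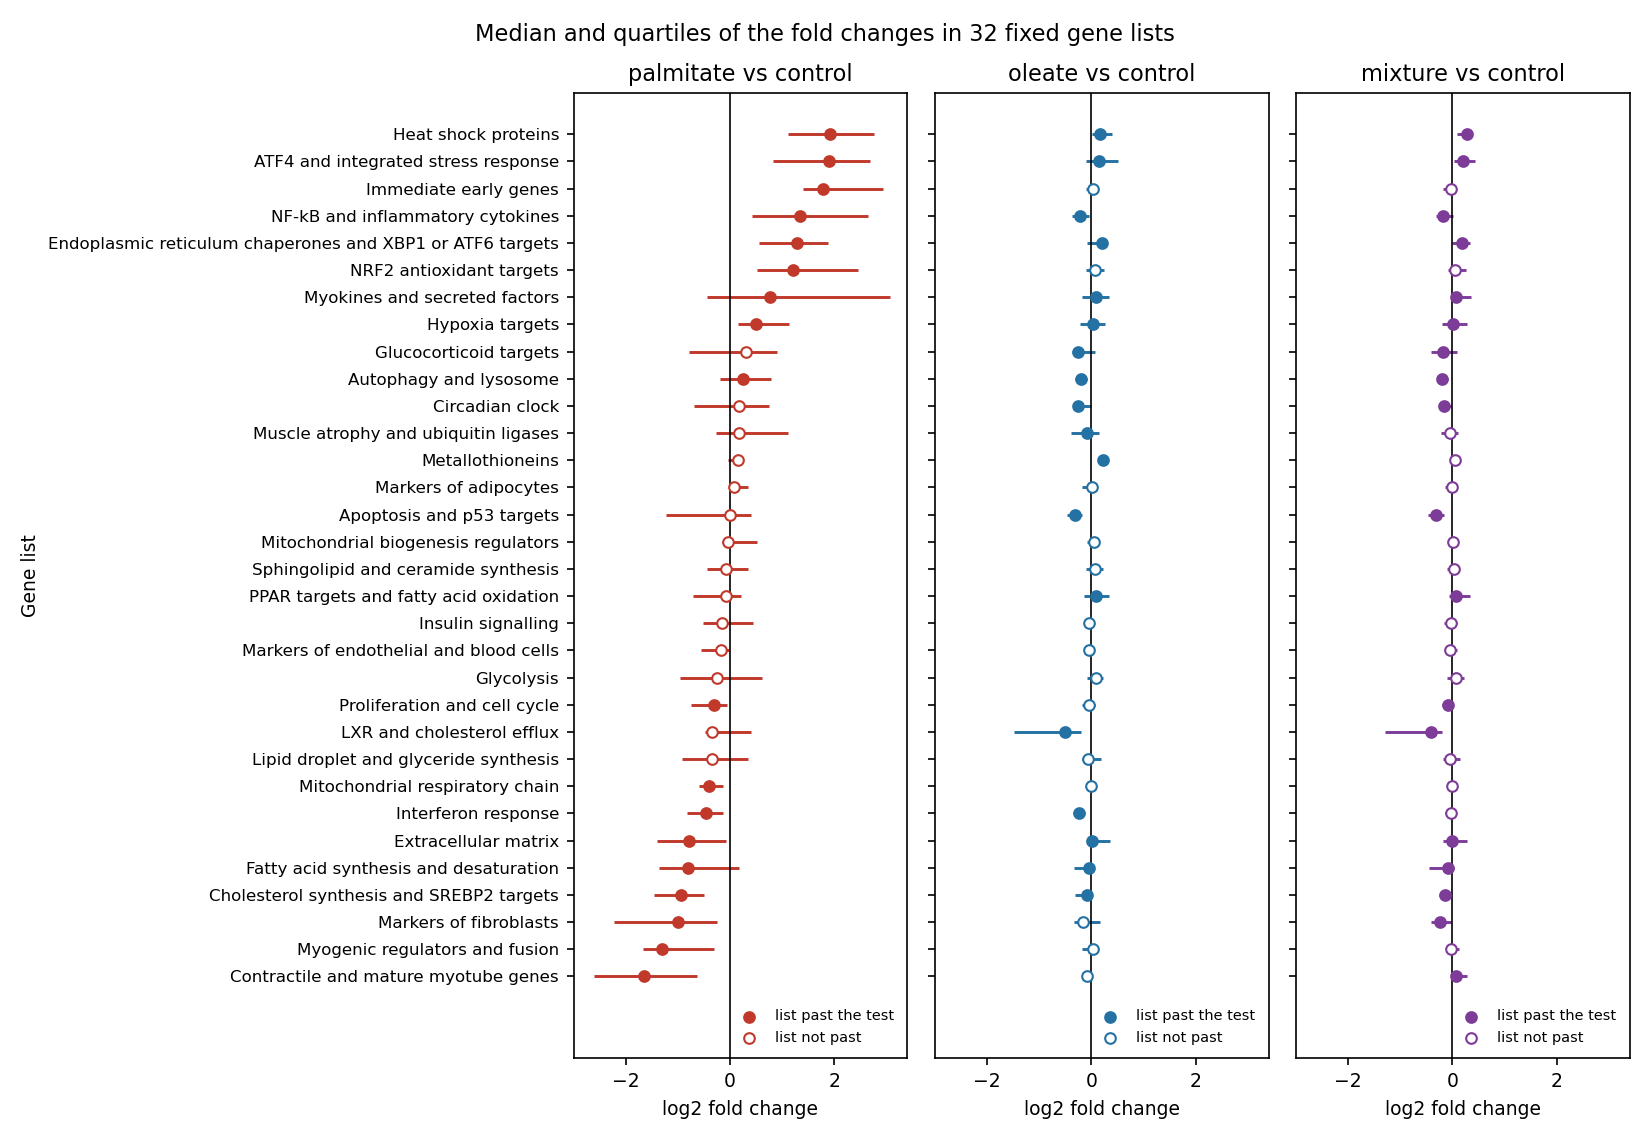
Median log2 fold change (points) with quartiles (lines) of the tested members of each of the 32 lists, against control, for palmitate, oleate and the mixture; filled points mark lists past the camera test with its preset correlation. Palmitate medians reached 1.92 for heat shock proteins and -1.66 for contractile genes, where those for oleate were 0.16 and -0.08.

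The effect of 0.5 mM oleate was asked by comparing it with control through the arrays that link them. ANGPTL4 rose 43.5-fold (5.44 ± 0.11, adjusted p = 1.1e-08), from a level of 8.40 ± 0.22 in control to 13.74 ± 0.12 (n = 4 each). CPT1A rose 4.65-fold (2.22 ± 0.14) and PDK4, above background in 2 of the 4 control channels, 3.71-fold (1.89 ± 0.06). The cholesterol exporter ABCA1 fell (-2.07 ± 0.08, adjusted p = 1.1e-06), as did MYLIP, a ubiquitin ligase under LXR control (-2.15 ± 0.10). IL6 (-0.26 ± 0.11, adjusted p = 0.16), CXCL8 (0.03, adjusted p = 0.81) and TRIB3 (0.24 ± 0.09, adjusted p = 0.086) did not pass. In IL6, 1 oleate RNA stood apart at a level of 10.94.

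With oleate, 4327 genes and unnamed probes changed (18.7%), 2190 higher and 2137 lower, and 55 of them by over 2-fold. After ANGPTL4 and CPT1A, the largest rises were those of KRTAP1-5 (1.97 ± 0.10), PDK4, DKK1 (1.64 ± 0.08), FGF1 (1.44 ± 0.07), ACTG2 (1.42 ± 0.06) and DDAH1 (1.39 ± 0.08). KRTAP1-5 belongs to a family of near-identical genes, so its level is uncertain. After MYLIP and ABCA1, large falls included those of SREBF1 (-2.02 ± 0.06), TNFSF10 (-1.72 ± 0.16), TMT1A (-1.46), FADS2 (-1.39 ± 0.05) and SCD (-1.35 ± 0.08). SREBF1 was read from its brightest probe, and its other probe stood at 0.15 and did not pass. The level of SCD was apart in 1 oleate RNA, at 9.59. PLIN2 rose by 0.42 ± 0.07 and INSIG1 fell by 0.50, with 1 oleate RNA of INSIG1 apart at 11.93. DDIT3 fell by 0.53 ± 0.11, a call lost with Feature Extraction log ratios and without a dye intercept. HMGCS1 (0.04) did not pass.

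Camera passed 18 lists for oleate against control. With an estimated correlation 0 of them held and 6 had an unadjusted p under 0.05. LXR and cholesterol efflux genes fell (8 of 11, 1 higher, 9 lower when adjusted over the list alone; median -0.50, -0.97 to -0.43 over the settings, adjusted p = 5.4e-29), including LPCAT3 (-0.93). Their adjusted p = 0.0746 with an estimated correlation. Apoptosis and p53 targets fell (16 of 21, 0 higher, 1 higher when adjusted over the list alone; median -0.32), DDB2 at -0.88 and SESN1 at -0.71 (adjusted p = 0.0746 with an estimated correlation). PPAR targets and fatty acid oxidation genes rose (10 of 33, 4 lower, 12 higher when adjusted over the list alone; median 0.09, 0.05 to 0.11 over the settings), SLC25A20 by 1.04 (adjusted p = 0.152 with an estimated correlation). Fatty acid synthesis and desaturation genes fell (8 of 19, 4 higher, 9 lower when adjusted over the list alone; median -0.03, -0.11 to -0.01 over the settings, mean -0.30), FADS1 at -1.02 (adjusted p = 0.344 with an estimated correlation). ATF4 and integrated stress response genes rose (12 of 28, 5 lower; 13 and 6 when adjusted over the list alone; median 0.15), PSAT1 by 0.99 and SLC7A5 by 0.84, whereas DDIT4 fell by 0.68 (adjusted p = 0.164 with an estimated correlation). Endoplasmic reticulum chaperones rose (13 of 29, 1 lower; 17 and 2 when adjusted over the list alone; median 0.21; adjusted p = 0.147 with an estimated correlation).

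NF-kB and inflammatory cytokines fell with oleate (16 of 33, 1 higher; 18 and 2 when adjusted over the list alone; median -0.22), TLR2 at -0.84 (adjusted p = 0.344 with an estimated correlation). Interferon response genes fell (10 of 23, 0 higher, 13 lower when adjusted over the list alone; median -0.23), CXCL10 at -0.99 (adjusted p = 0.344 with an estimated correlation). Autophagy and lysosome genes fell (13 of 25, 0 higher; 15 and 1 when adjusted over the list alone; median -0.20, -0.22 to -0.12 over the settings; adjusted p = 0.152 with an estimated correlation). Heat shock proteins rose (9 of 20, 0 lower, 1 lower when adjusted over the list alone; median 0.16), DNAJB4 by 0.69 (adjusted p = 0.312 with an estimated correlation). The remaining 8 calls had adjusted p from 0.344 to 0.686 with an estimated correlation. Called higher among them were myokines (6 of 18, 2 lower), hypoxia targets (6 of 19, 5 lower; median 0.04, 0.02 to 0.11 over the settings; ADM 0.95), extracellular matrix genes (10 of 29, 2 lower; median 0.01, -0.00 to 0.08 over the settings; COL1A1 0.70) and metallothioneins (2 of 11, 8 when adjusted over the list alone). The hypoxia list also holds ANGPTL4, the largest rise with oleate, and how far the call rests on that gene was not tested. Called lower were the circadian clock (9 of 17, 2 higher; BHLHE41 -0.73), cholesterol synthesis (9 of 28, 3 higher; LPIN1 -0.74) and muscle atrophy genes (7 of 16, 3 higher). Glucocorticoid targets were called higher by the test and had a mean of 0.32 but a median of -0.26, with 2 of 14 higher and 8 lower, and with scale normalization the test turned lower and did not pass (median -0.22). Adjusted over the list alone, the counts higher and lower became 8 and 4 for myokines, 7 and 7 for hypoxia, 10 and 4 for extracellular matrix, 3 and 11 for the clock, 4 and 7 for atrophy genes and 3 and 9 for glucocorticoid targets. The calls for hypoxia and for cholesterol synthesis were lost with scale normalization and with median centring respectively, and those for atrophy genes and glucocorticoid targets with Feature Extraction log ratios. That for glucocorticoid targets was also lost with probes above background in all 16 channels. That for atrophy genes was also lost with median centring, without replicate 2 of the oleate and mixture arrays, and without replicate 1 of the mixture and control arrays. Contractile genes (5 of 43 higher, 7 lower; median -0.08, adjusted p = 0.564) and lipid droplet genes (5 of 25 higher, 6 lower; adjusted p = 0.762) were among the 14 lists that did not pass.

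The number of genes changed with oleate depended on the fit. It was 1395 without a dye intercept, 1758 with median centring and 2810 with scale normalization.

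The effect of the mixture was asked by comparing it with control, with which it shared 2 arrays. ANGPTL4 rose 40.0-fold (5.32 ± 0.09, adjusted p = 3.4e-09), CPT1A 4.12-fold (2.04 ± 0.12) and PDK4, with the same control channels, 3.79-fold (1.92 ± 0.06). ABCA1 (-1.90 ± 0.07) and SCD (-1.22 ± 0.07) fell. IL6 (0.13, adjusted p = 0.44) and CXCL8 (0.01, adjusted p = 0.92) did not pass. TAGLN, an actin-binding protein of contractile cells, rose by 1.43 ± 0.07.

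With the mixture 4535 genes and unnamed probes changed (19.6%), 2307 higher and 2228 lower, and 49 of them by over 2-fold. The other large rises were those of KRTAP1-5 (1.91 ± 0.08), FGF1 (1.56), DDAH1 (1.53) and ACTG2 (1.52), and other large falls included those of MYLIP (-1.93 ± 0.08), SREBF1 (-1.84 ± 0.06), RAB26 (-1.36), RASD1 (-1.33) and TNFSF10 (-1.28). The other probe of SREBF1 passed in the opposite direction (0.22), so its direction depends on the probe. INSIG1 fell by 0.48. PLIN2 (0.29 ± 0.06), TRIB3 (0.26 ± 0.08), HMGCS1 (-0.19 ± 0.05) and DDIT3 (-0.34 ± 0.09) passed. The call of PLIN2 was lost without either array of the mixture with control, and those of TRIB3, HMGCS1 and DDIT3 under 11, 7 and 8 of 21 other settings. The count was 1645 without a dye intercept, 2031 with median centring (1243 higher and 788 lower) and 2164 without replicate 2 of the mixture and control arrays.

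Camera passed 18 lists for the mixture. With an estimated correlation 0 held and 8 had an unadjusted p under 0.05. LXR and cholesterol efflux genes fell (8 of 11, 0 higher; median -0.40, -0.75 to -0.31 over the settings) and p53 targets fell (15 of 21, 1 higher, 16 lower when adjusted over the list alone; median -0.31), each with an adjusted p = 0.0626 with an estimated correlation. Endoplasmic reticulum chaperones rose (14 of 29, 2 lower, 18 higher when adjusted over the list alone; median 0.18; adjusted p = 0.0626 with an estimated correlation). ATF4 and integrated stress response genes rose (15 of 28, 5 lower, 16 higher when adjusted over the list alone; median 0.21), ASNS by 1.18 and SLC7A5 by 1.06 (adjusted p = 0.0845 with an estimated correlation). PPAR targets rose (11 of 33, 2 lower; 12 and 3 when adjusted over the list alone; median 0.07, 0.06 to 0.13 over the settings), SLC25A20 by 1.02 (adjusted p = 0.092 with an estimated correlation). Heat shock proteins rose (11 of 20, 0 lower, 12 higher when adjusted over the list alone; adjusted p = 0.171 with an estimated correlation). Contractile genes rose (12 of 43, 5 lower, 15 higher when adjusted over the list alone; median 0.06, 0.03 to 0.12 over the settings), TPM2 by 1.00 and MYH2 by 0.88. Their adjusted p = 0.615 with an estimated correlation, and the call was lost without replicate 2 of the mixture and control arrays. The 11 other calls had adjusted p from 0.104 to 0.736 with an estimated correlation. Called higher were myokines (5 of 18, 2 lower), hypoxia targets (6 of 19, 5 lower; median 0.01, -0.06 to 0.10 over the settings; ADM 1.22), extracellular matrix (10 of 29, 4 lower; CCN2 1.30, CCN1 1.10) and glucocorticoid targets (3 of 14, 6 lower). Here too the hypoxia list holds ANGPTL4, the largest rise with the mixture. Called lower were fatty acid synthesis (8 of 19, 2 higher; FADS2 -1.02), cholesterol synthesis (12 of 28, 1 higher), autophagy (12 of 25, 0 higher), NF-kB (14 of 33, 0 higher), fibroblast (6 of 12, 1 higher), cell cycle (7 of 33, 3 higher) and circadian genes (7 of 17, 3 higher). The fibroblast call was lost without replicate 1 of the mixture and control arrays, and the cell cycle and circadian calls without either of these arrays. The cell cycle call was also lost without a dye intercept, the circadian call with scale normalization, and the circadian and glucocorticoid calls with Feature Extraction log ratios and with probes above background in all 16 channels. In the extracellular matrix list the median was -0.00 and the mean 0.15. In glucocorticoid targets the median was -0.17 and the mean 0.32, and with scale normalization the test turned lower and did not pass (median -0.18).

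**Figure D3:**
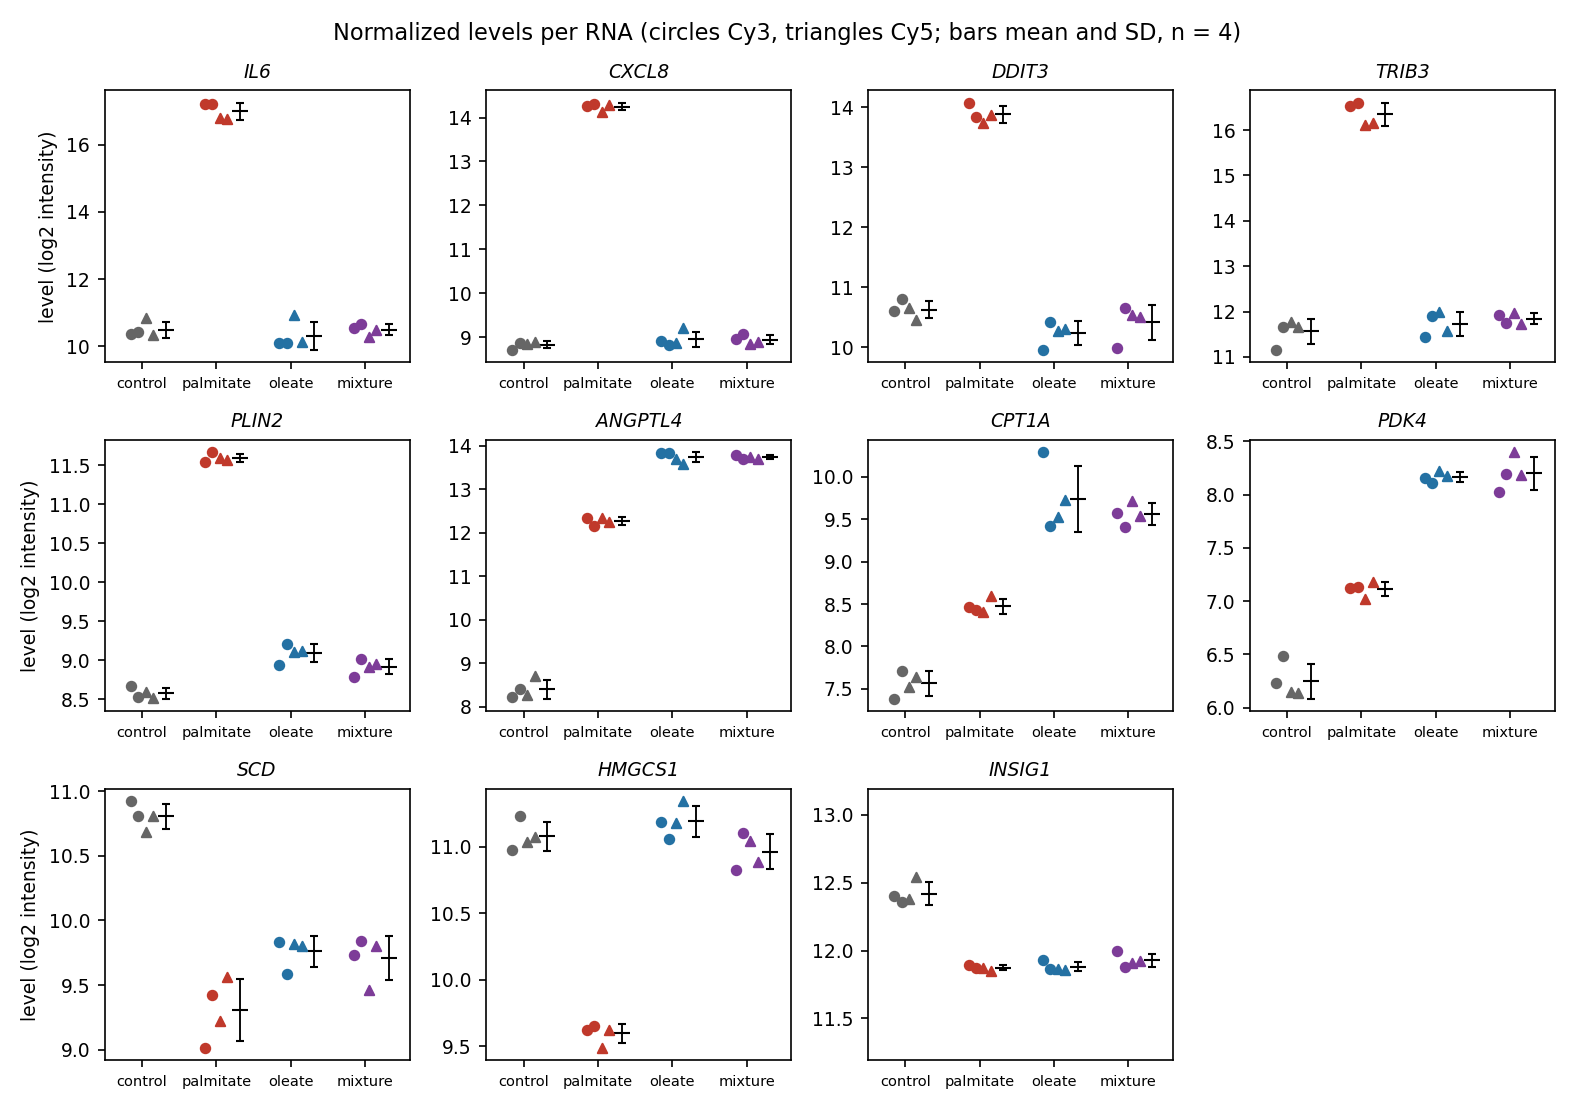
Normalized log2 level (vertical axis) of 11 genes fixed in advance in each of the 16 RNAs by condition, circles for Cy3 and triangles for Cy5, with the mean and SD of 4 RNAs at the right of each group. IL6 averaged 16.99 with palmitate and 10.49 in control, while ANGPTL4 averaged 13.74 with oleate and 12.27 with palmitate.

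Whether the saturated and the unsaturated fatty acid differed at one dose was asked by comparing palmitate with oleate. IL6 was 94.7-fold higher with palmitate (6.57 ± 0.10), CXCL8 42.3-fold, DDIT3 13.7-fold (3.77 ± 0.09) and PLIN2 5.90-fold (2.56 ± 0.06). ABCA1 was higher by 3.39 ± 0.07 (adjusted p = 2.6e-10). ANGPTL4 (-1.46 ± 0.09, adjusted p = 2.5e-07), CPT1A (-1.32 ± 0.12) and PDK4 (-1.02 ± 0.06), which both fatty acids raised, were lower with palmitate than with oleate. ACTA1 (-3.61 ± 0.09) and MYH7 (-3.47) of the contractile apparatus were lower as well.

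Between palmitate and oleate 14453 genes and unnamed probes differed (62.5%), 7077 higher and 7376 lower with palmitate, 2506 of them by over 2-fold. The 8 largest rises were IL6, CCL3 (6.16), CXCL8 (5.40 ± 0.05), C11orf96 (5.37), CCL20 (5.37), HSPA6 (5.17), CSF3 (5.07) and TRIB3 (4.64 ± 0.08). The 8 largest falls were ACTA1, CDKN1C (-3.57), DMBT1 (-3.49), MYH7, MYH3 (-3.33), MEST (-3.24), HEYL (-3.19) and MYH8 (-3.04). HMGCS1 (-1.52) was lower and INSIG1 (-0.02, adjusted p = 0.74) did not pass. SCD was lower (-0.34 ± 0.07), a call lost with scale normalization.

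Of the 18 list calls for palmitate against oleate, those of ATF4 targets (24 of 28 higher, 3 lower; median 1.57) and endoplasmic reticulum chaperones (25 of 29 higher, 2 lower, 26 higher when adjusted over the list alone; median 1.10) held with an estimated correlation (adjusted p = 0.0463 each). NF-kB genes were higher with palmitate (27 of 33, 5 lower; median 1.78; adjusted p = 0.185 with an estimated correlation) and contractile genes lower (37 of 43, 2 higher; median -1.65; adjusted p = 0.175 with an estimated correlation). PPAR targets were lower with palmitate (21 of 33, 5 higher; median -0.49, adjusted p = 8.3e-04), among them UCP2 (-2.05), HADH (-1.74) and SLC25A20 (-1.58), and their adjusted p = 0.117 with an estimated correlation. LXR and cholesterol efflux genes were higher (7 of 11, 3 lower; median 0.47), including SREBF1 (1.62) and MYLIP (1.67), with an adjusted p = 0.185 with an estimated correlation. The 12 other calls, of which that for the respiratory chain was lost with median centring, had adjusted p from 0.0845 to 0.513 with an estimated correlation and, the balanced myokines (9 of 18 each way) aside, the directions of palmitate against control.

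Whether replacing part of the palmitate by oleate at one total dose changed the profile was asked by comparing the mixture with palmitate. IL6 (-6.18 ± 0.11), CXCL8 (-5.42 ± 0.06), TRIB3 (-4.62) and PLIN2 (-2.70 ± 0.07) were lower with the mixture. MYH7 was 15.5-fold higher (3.95 ± 0.09, adjusted p = 9.7e-10), followed by ACTA1 (3.92 ± 0.10), MYH3 (3.73 ± 0.07) and MYH8 (3.48). ANGPTL4 (1.34 ± 0.11), CPT1A (1.14 ± 0.14) and PDK4 (1.05 ± 0.06) were also higher with the mixture. In all 13515 genes and unnamed probes differed (58.4%), 7033 higher and 6482 lower, and 2547 by over 2-fold. The largest falls after IL6 were CCL3 (-5.69), C11orf96 (-5.53) and CXCL8. Camera passed 19 lists. ATF4 targets (24 of 28 lower, 3 higher; median -1.53) and endoplasmic reticulum chaperones (25 of 29 lower, 2 higher; median -1.07) held with an estimated correlation (adjusted p = 0.0444 each). Contractile genes were higher with the mixture (36 of 43, 2 lower, 37 higher when adjusted over the list alone; median 1.73; adjusted p = 0.157 with an estimated correlation). NF-kB genes were lower (27 of 33, 5 higher; median -1.60; adjusted p = 0.19 with an estimated correlation). The 15 other calls, among them higher cholesterol synthesis (23 of 28, 0 lower) and myogenic genes (19 of 23, 1 lower), had adjusted p from 0.0762 to 0.497 with an estimated correlation. Among them the interferon call was lost without a dye intercept, the cell cycle call with scale normalization, and the respiratory chain call with median centring and with probes above background in all 16 channels.

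Whether replacing part of the oleate by palmitate changed the profile was asked by comparing the mixture with oleate. RNF145, a sterol-responsive ubiquitin ligase, was 2.86-fold lower with the mixture (-1.51 ± 0.07, adjusted p = 2.8e-05). B4GALT5, which makes lactosylceramide, was lower as well (-1.07 ± 0.05), as were the surface protein CD24 (-0.84 ± 0.05) and UGCG (-0.80 ± 0.06), which makes glucosylceramide. The fast myosin heavy chain MYH2 was 1.76-fold higher (0.82 ± 0.07, adjusted p = 0.00064) and the matricellular gene CCN2 was higher by 0.60 ± 0.05. The largest changes by the fixed rule also held TPD52L1 (0.55) and PKP2 (0.53), whose calls were lost under 3 and 6 of 22 other settings, and NPTX1 (-0.93 ± 0.10). RNF145, B4GALT5 and CD24 passed under every setting tried, MYH2 and CCN2 under all but Feature Extraction log ratios, and UGCG and NPTX1 under all but those and the fit without a dye intercept. IL6 (0.38 ± 0.10, adjusted p = 0.15), ANGPTL4 (-0.12), CPT1A (-0.17) and PDK4 (0.03) did not pass.

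Between mixture and oleate 171 genes and unnamed probes differed (0.739%), 81 higher and 90 lower, and 2 by over 2-fold. At an unadjusted p under 0.05 there were 2746. The balance of directions depended on the fit. The count was 9 with Feature Extraction log ratios (all lower), 16 without a dye intercept (3 higher), 33 from direct arrays alone (10 higher), 18 without replicate 1 of the oleate and mixture arrays (4 higher), 54 without replicate 2 of them (19 higher), 47 without replicate 2 of the palmitate and control arrays (15 higher), 296 with scale normalization (169 higher) and 782 in a fit of separate channels (379 higher). Camera passed 7 lists. With an estimated correlation 0 held and 2 had an unadjusted p under 0.05, and by fry, which asks whether members move one way, 1 passed. Contractile genes were higher (6 of 43, 0 lower, 19 higher when adjusted over the list alone; median 0.14), with MYH7 at 0.48 and MYH3 at 0.40, each a call lost under 11 of 22 other settings (adjusted p = 0.486 with an estimated correlation). Interferon response genes were called higher with a median of 0.20, although only 1 of 23 members passed (0 lower, 14 higher when adjusted over the list alone). Their adjusted p = 0.486 with an estimated correlation. Metallothioneins were called lower, although 0 of 11 members passed (5 when adjusted over the list alone). Sphingolipid genes were called lower as well (2 of 25, 3 when adjusted over the list alone). Each had an adjusted p = 0.486 with an estimated correlation. The calls for immediate early (1 of 22 higher, 2 lower), atrophy (1 of 16 higher) and cholesterol synthesis genes (1 of 28 lower) had adjusted p of 0.561, 0.538 and 0.586 with an estimated correlation. These calls were lost under 3, 7 and 9 of 23 other settings in all, that of immediate early genes without replicate 1 of the oleate and mixture arrays.

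Whether the mixture lay midway between its components was asked by testing it against the mean of palmitate and oleate on the log2 scale. It lay off that midpoint for 10111 genes and unnamed probes (43.7%), 5403 above it and 4708 below, 394 of them by over 2-fold. IL6 (-2.90 ± 0.09), C11orf96 (-2.85), CXCL8 (-2.72 ± 0.05) and CCL3 (-2.61) lay farthest below, and MYH7 (2.22 ± 0.07), ACTA1 (2.12 ± 0.09), MYH3 (2.07 ± 0.06) and MYH8 (1.96) farthest above. PLIN2 lay below (-1.42 ± 0.05) and ANGPTL4 above (0.61 ± 0.09). CPT1A lay above by 0.49, a call lost without replicate 2 of the oleate and mixture arrays. Camera passed 18 lists. ATF4 targets (22 of 28 below, 3 above; median -0.78) and endoplasmic reticulum chaperones (25 of 29 below, 2 above; median -0.52) held with an estimated correlation (adjusted p = 0.0385 each). Contractile genes lay above (36 of 43, 1 below; median 0.93; adjusted p = 0.141 with an estimated correlation). Myokines were called below with a mean of -0.45 but a median of 0.08 (-0.43 with probes above background in all 16 channels), and their adjusted p = 0.444 with an estimated correlation. The 14 other calls had adjusted p from 0.0625 to 0.392 with an estimated correlation. Among them that of the respiratory chain (adjusted p = 0.0471) was lost under 10 of 21 other settings in all. That of LXR targets was lost with the mean of all probes of a gene and without replicate 1 of the oleate and mixture arrays. All comparisons that involve palmitate rest on the same palmitate RNAs. As the mixture differed little from oleate, the calls against the midpoint and against palmitate largely repeat those of palmitate against oleate. They are not separate evidence for an effect of palmitate.

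How alike the effects were was asked by correlating log2 fold changes across genes, which are not independent replicates. The effects of oleate and of the mixture against control correlated at r = 0.892, and their covariance was 0.0373. Simulated data with no effect gave 0.577 and 0.00281, through the arrays of the loop that both estimates use. Of the genes that changed in both, 1655 were higher in both, 1588 lower in both and 9 opposite. If the calls were independent, 218.4 would be higher in both and 205.8 lower in both, but shared arrays also favour a common sign. Palmitate and oleate effects correlated at r = 0.341 against 0.577 with no effect, with a covariance of 0.0497 against 0.00281. They were higher in both for 1303 genes, lower in both for 1511 and opposite for 897, where independent calls would give 660.3 higher and 699.5 lower in both. Palmitate and mixture effects correlated at r = 0.333 against 0.331 with no effect, with a covariance of 0.0441 against 0.0014. On arrays with no RNA in common, palmitate and mixture effects correlated at r = 0.322, with a slope of the mixture effect of 0.0946. As the labels do not state whether the control medium held albumin, an effect of albumin is not separated from what the comparisons with control share.

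**Figure D4:**
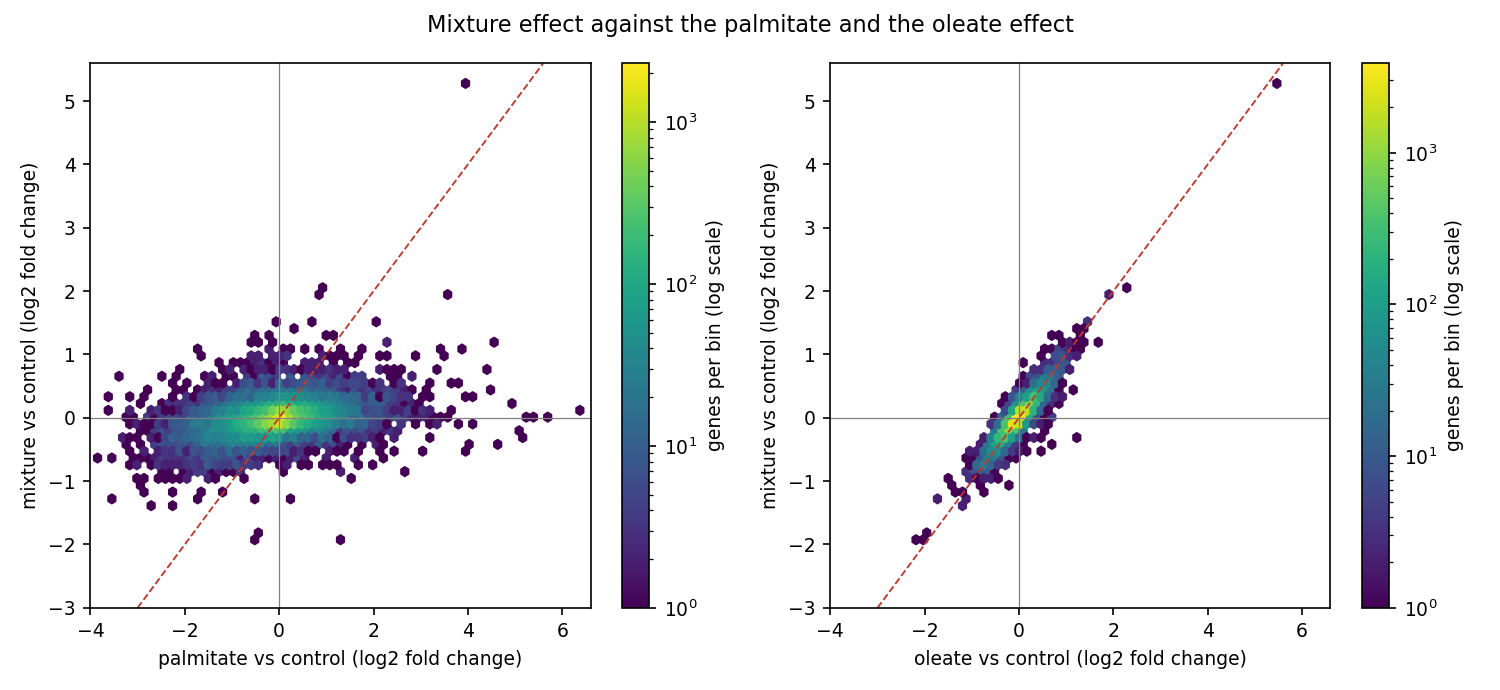
Log2 fold change of the mixture against control (vertical axis) by that of palmitate (left) and of oleate (right) against control for each gene tested, coloured by genes per bin on a log scale; the dashed line marks equal effects. The mixture and oleate effects correlated at r = 0.892 (0.577 simulated with no effect) and the mixture and palmitate effects at r = 0.333 (0.331 simulated). The simulated r comes from noise alone, as the fitted comparisons share arrays. The covariance of mixture and palmitate effects was 0.0441 against 0.0014 simulated, and on arrays with no RNA in common r was 0.322.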

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

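A closer look went to any RNA whose gap to its neighbour took up more of the range of its group of 4 than Dixon's critical value allows. The rule was fixed before the data were examined, and it was applied to 11 genes named in advance and to the share of spots above background in each condition, 48 groups in all. Chance marks about 1 group in 20, and 5 of the 48 were marked.

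IL6 in control had a level of 10.842 in replicate 2, while the next RNA lay at 10.415. IL6 in oleate had 10.935 in replicate 1, while the next lay at 10.134. Both values were far from the 16.99 of palmitate. These 2 RNAs shared their arrays with palmitate RNAs at 17.2 and 17.219, where the other palmitate RNAs lay at 16.789 and 16.771. The level of the array is thus not separated from that of the RNA. SCD in oleate was at 9.5856 in replicate 4, under the 9.8046 to 9.832 of the others. INSIG1 in oleate was at 11.933 in replicate 2, while the next lay at 11.866. The share of spots above background in the mixture was 62.444% in replicate 2, while the next lay at 65.734%. No biological explanation was tested for these 5 values, and the design names none within a condition.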

How the results depend on the processing

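The dye term per slide column and median centring were chosen after the data had been seen, and the other alternatives before the data were examined. A block for the slide was not run, since all arrays lay on 1 slide. The replicate block was fitted for the 2 of 7 comparisons that it allowed, and left 3 residual degrees of freedom. Residuals of the 2 pairs of arrays with the same difference of numbers correlated at -0.311 and -0.262 across genes, above the -0.5 of independent samples. That is the direction pairing would give, but 2 pairs were too few to take the numbers as pairing the samples. Where an array was left out, the condition kept 3 RNAs and shared the pooled spread.

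Counts of genes kept within 1.5 times under every alternative for palmitate against control (11737 to 15692; 14991 with the replicate block), palmitate against oleate (11493 to 15645), mixture against palmitate (10395 to 15109), mixture against the midpoint (6802 to 11865) and any difference (11827 to 16680). Oleate against control fell to 2810 with scale normalization, 1395 with no dye intercept and 1758 with median centring. Mixture against control fell to 1645 with no dye intercept and 2031 with median centring, and ranged from 2164 (without replicate 2 of the mixture and control arrays) to 4638 with 1 array left out. Mixture against oleate gave 9 genes with Feature Extraction log ratios, 56 with the deposited value table, 16 with no dye intercept, 79 with the dye term per slide column, 69 with median centring and 33 from direct arrays alone. It gave 296 with scale normalization, 263 with the replicate block and 782 with separate channels. With 1 array left out it ranged from 18 (without replicate 1 of the oleate and mixture arrays) to 133 (without replicate 1 of the mixture and control arrays). The cause of these shifts, and of the reversals given next, was not tested, although scale normalization shrinks the palmitate arrays by its construction. No setting moved the median of all genes by more than 0.1 on the log2 scale. That could hardly be otherwise, as the ratios were balanced within each array under every setting and the deposited value table was centred as well. It says nothing about a shift shared by most genes.

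The genes that reversed were small changes that had not passed. With scale normalization CXCL8 in the mixture against control became -0.00672, and INSIG1 became 0.0403 for palmitate against oleate, -0.0510 for mixture against palmitate, -0.0107 for mixture against oleate and -0.0308 against the midpoint. Mixture against oleate became 0.437 for ANGPTL4 and 0.0274 for CPT1A under it. With median centring INSIG1 became 0.0494 for palmitate against oleate and -0.0196 for mixture against palmitate. CXCL8 became -0.00174 for mixture against control with array quality weights, and PDK4 -0.0101 for mixture against oleate with Feature Extraction log ratios. The medians of glucocorticoid targets, called higher, were -0.225 (oleate) and -0.176 (mixture) with scale normalization, under which the test turned lower and did not pass.

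With 1 array left out CXCL8 ranged from -0.0208 to 0.0692 for oleate against control, from -0.0271 to 0.0355 for mixture against control and from -0.0787 to 0.0563 for mixture against oleate. INSIG1 ranged from -0.0429 to 0.0242 for palmitate against oleate. For mixture against oleate PDK4 ranged from -0.00397 to 0.0565, INSIG1 from -0.00255 to 0.0401 and TRIB3 from -0.0984 to 0.171.

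Of the calls of named genes, 78 were lost with no dye intercept, 60 with median centring, 41 with Feature Extraction log ratios and 21 with scale normalization. An estimated correlation lost 108 list calls, and fry lost 6 and added 55. Between 62.4% and 67.9% of spots stood above background, and genes under it were not tested.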

Other observations

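Tests of a palmitate effect in proportion to its concentration, of oleate acting against palmitate, of a smaller share of myotubes, and of loess normalization by median centring were chosen only after the results they bear on had been seen.

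Probes for long intergenic noncoding RNA were tested without gene names, and 814 of 3768 were higher and 581 lower with palmitate than in control. With oleate 73 were higher and 138 lower, and with the mixture 106 and 114. The largest rises with palmitate on hg19 were at chromosome 7, 130589527 to 130590094 (2.83 ± 0.19), and at chromosome 11, 17370980 to 17371527 (2.58 ± 0.06). Neither passed with oleate (-0.04 and -0.02) or with the mixture. The largest falls were at chromosome 14, 96507172 to 96661947 (-2.51 ± 0.06) and, within that span on the same strand, 96548697 to 96561747 (-2.50 ± 0.05). They may therefore be readings of a single locus. At chromosome 3, 112308735 to 112318605, the RNA fell by 2.20 with palmitate and rose by 0.68 with oleate and 0.52 with the mixture. A second probe there (112315643 to 112316945) gave -2.20, 0.60 and 0.50.

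A set of actin cytoskeleton genes was picked out after their values were seen. ACTA2 fell with palmitate (-1.80) and rose with oleate (0.78) and with the mixture (1.10), and MYL9 did likewise (-0.47, 0.77 and 0.98). ACTB stood at -0.26, 1.03 and 1.13 in the same order, and TAGLN at 0.32, 1.33 and 1.43. For ACTG2 the change with palmitate did not pass (-0.11), and those with oleate and the mixture were 1.42 and 1.52. CERT1, a ceramide carrier picked the same way, was lower (-0.82) in the mixture than with oleate, beside RNF145, B4GALT5 and UGCG.

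The mixture lay close to oleate and off the midpoint of palmitate and oleate. A palmitate effect in proportion to its concentration would give a slope of 0.5 of mixture minus oleate on palmitate minus oleate, and the slope on arrays with no RNA in common was 0.00183 (-0.0383 to 0.0414 over pairs of single arrays). Oleate RNA on the arrays in place of mixture RNA would leave no more genes than other splits, and 171 were called against at most 3, while loess normalization is argued against by a slope of 0.00250 with median centring (-0.205 to 0.215). Oleate acting against palmitate and palmitate being too dilute to act cannot be told apart, since 0 RNA samples had 0.25 mM palmitate alone. A biological response that may need more than 0.25 mM palmitate, or that oleate may block, is a hypothesis these data leave open.

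Contractile and myogenic genes were lower with palmitate. A smaller share of myotubes among the cells would raise the genes of other cells, unless palmitate itself lowered those genes. Markers of fibroblasts, of which 12 of 13 were tested in these cultures, had an upper quartile of -0.258, and COL1A1 went from a level of 14.56 to 12.53. The upper quartile was -0.0496 for cell cycle genes and -0.0856 for extracellular matrix genes. As palmitate may lower such genes in any cell of the line, these lists cannot decide on the share of myotubes. A bias against bright probes is argued against by 0 of 10000 random lists matched on intensity with a median at or below -1.66 (lowest -0.407). With median centring the contractile median was -1.54, which argues against loess normalization as the whole cause. A loss of muscle gene expression within the myotubes and a smaller share of myotubes both remain hypotheses, which single-cell data or protein could test.

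ANGPTL4, PDK4 and CPT1A rose less with palmitate than with oleate. Compression of ratios by the background correction draws differences toward 0, so it could hide this difference but hardly make it. Other ratios were therefore no real test of that cause. They show that the difference held, between -1.53 and -1.11 for all 3 genes over 3 other kinds of ratio. If fewer responding cells were the cause, nearly all of the 35 genes raised over 2-fold by the mixture would be lower with palmitate than with oleate. On the direct arrays 62.9% were, against 47.8% of all genes in the loop fit. The 13 that were higher were also raised by palmitate against control, such as DKK1 (4.57) and CCN1 (3.93). Genes that palmitate raises by another route would break the prediction in any case, so the share cannot decide on the number of responding cells. A weaker response of these 3 genes to palmitate could be biological and is offered as a hypothesis only. It is not shown for PPAR targets at large, as PLIN2, another of them, was higher with palmitate than with oleate (2.56 ± 0.06) and the list call was lost with an estimated correlation.

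Other splits of the same RNAs were fitted where the loop allowed, 33 or 34 of 35 for each pair of conditions, with 1 or 2 that could not be fitted. The real split called the most genes in palmitate against control (14542, highest other 0), oleate against control (4326, 303) and mixture against control (4530, 0). It did so too in palmitate against oleate (14448, 0), mixture against palmitate (13507, 0) and mixture against oleate (171, 3). The smallest share that 35 splits can reach is 0.0286 per comparison, so chance is made unlikely rather than excluded. Splits that mix conditions also hold the real effects in their residual spread, which lowers their counts. For any difference among the 4 conditions the real grouping called the most as well (15169, highest other 7332, over 90 drawn groupings, with 10 not fitted). For the midpoint 2 of 95 groupings, the real one included, reached the real 10108, and the other reached 13556, with 5 not fitted. That grouping put 2 oleate and 2 mixture RNAs in the place of the mixture and 3 of the 4 palmitate RNAs together. The 2 other drawn groupings of that make-up called 0 genes, and what sets it apart was not tested. The real split also passed the most lists in palmitate against control (18, highest other 16), oleate against control (18, 15) and mixture against control (18, 15). The same held in palmitate against oleate (18, 17) and mixture against palmitate (19, 17). The lead over other splits was 1 to 3 lists, and a split of palmitate and oleate RNAs that called 0 genes still passed 17 lists. These counts therefore hardly bear on chance and say nothing for any single list. Chance cannot be excluded for the count of lists in mixture against oleate, where 6 of 34 splits, the real one included, called at least the real 7 lists and the highest other called 10.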
